A study of Homo sapiens with 24 samples.

How the data were processed

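A549 cells were grown in F12K medium with 10% fetal bovine serum, plated at 35000 cells per well in 24-well plates, kept overnight in serum-free medium and then stimulated overnight without serum, per the labels. Iron and Ent were mixed 30 minutes before use and Lcn2 was added for 30 minutes more, and Ent came from more than 1 supplier, with no record of which array received which. Labelled targets were made from 150 ng of total RNA and hybridised to 24 Affymetrix whole-transcript arrays (Human Gene 1.0 ST), 1 per biological replicate. The labels state no batch within either experiment and treat the replicates of a group as exchangeable.

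The authors reduced the scanned arrays by RMA (robust multi-array average, version not given in the sources used here) to 29096 non-control probe sets. The deposited values are log2 signals, per the labels and per the file headers. The deposited workbook also holds each p-value of the authors' F tests, not adjusted for multiple testing, and each fold change of the authors as a linear ratio of group means. The value table and the workbook held the same signals. When each array's values were sorted, no array departed from the mean of the sorted arrays by more than 0.147. Quantile normalization over both experiments together would leave such values, but the closeness does not settle whether they were normalized together. No genome build is given, so no coordinates are reported.

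Gene symbols came from the deposited annotation and were updated through Entrez identifiers: 20871 probe sets had an identifier, 20551 of these matched the reference table, and 3381 symbols changed. Probe sets with 1 gene assigned numbered 19030, with several 2577 and with none 7489. Genes read by a probe set that several genes share are counted in their lists but not named. The probe sets of named genes with their identifiers were taken as the files give them.

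All comparisons were fitted with limma 3.58.1 in R 4.3.3, as linear models of group means with moderated variances, on the deposited log2 values with no filter. Experiment 1 and experiment 2 were fitted apart (4 and 12 residual degrees of freedom, with a prior of 4.8 and 4.59), and a fit over all 24 arrays (16 residual, prior 4.91) gave the differences of effects across experiments. The p-values were adjusted by Benjamini and Hochberg within each of the 12 comparisons, and a probe set was called at an adjusted p under 0.05, two-sided. The standard error of a difference is that of the moderated fit. It rests on a single variance per probe set, shared by all groups of the fit. It therefore does not widen for a group whose arrays vary more than the others. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

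The comparisons, the main settings, the alternatives, the 27 gene lists and the rule for named genes were chosen before the data were examined. The lists cover HIF targets, glycolysis, iron handling, iron-sulfur cluster assembly, cytokines and chemokines, NF-κB feedback, epithelial defence, interferon response, DNA replication, mitosis, p53 targets, the amino acid response through ATF4, the unfolded protein response, NRF2 targets, metallothioneins and zinc transport, cholesterol synthesis, oxidative phosphorylation, ribosome biogenesis, heat shock, apoptosis, autophagy, type II pneumocytes, matrix and mesenchymal genes, and markers of leukocytes, fibroblasts, endothelium and airway epithelium. Each list was tested with camera (preset correlation 0.01, adjusted over the 27 lists of a comparison), and again with an estimated correlation, with fry, after a filter on low signals and with a replicate block. The preset treats the genes of a list as nearly uncorrelated, so very small p-values from it overstate the evidence where they vary together. An adjusted p with an estimated correlation is printed only where it ended the call. Counts "adjusted over the list alone" apply Benjamini and Hochberg to a list's members only. The naming rule took, for each comparison, 17 anchor genes whether or not they passed, the 8 largest called differences in each direction, and up to 4 called members of each list with the largest differences. The largest differences were taken among probe sets with 1 symbol, a group mean above the median of all probe sets and, except for the interaction and the cross-experiment tests, values of the compared groups that did not overlap. A gene with several probe sets is represented by the one with the highest mean. The text prints part of the genes that the rule gave, and no gene was turned away for its direction, but in experiment 2 and across experiments genes whose call ended under an alternative were passed over. Some results of the rule are not reported here.

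The alternatives were cyclic loess on top of the deposited values, a filter on low signals (probe sets above the median of all), a variance prior with trend and robust fitting, no variance moderation, array weights, a replicate block, 1 probe set per gene symbol, a fit over all 24 arrays, a fit of the compared groups alone, a threshold of 1.5-fold beside the adjusted p, the authors' p-values after adjustment, and leaving out each array in turn. The overlap of comparisons that share a control group was set against 50 simulations of unchanged groups and the 6 ways to split the PBS group of experiment 2, and the 2 ways in experiment 1. The simulations drew independent values for each probe set around its mean, with its own SD. Group labels were also permuted over all 35 splits of 8 arrays, or 100 regroupings of the 16 arrays for the interaction. The fit was tested on simulated data of 50 changed probe sets per fold: at 1.3, 1.5, 2 and 4-fold it recovered 32, 45, 50 and 50 for groups of 4, and 8, 31, 46 and 50 for groups of 2, with 7 and 8 false calls.

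The array median was 6.48 to 6.65 on the log2 scale, and the number of arrays, 2 per group in experiment 1 and 4 in experiment 2, limits the precision. In the authors' p-values for experiment 2, the denominator has 16 degrees of freedom although the mean square is divided by 12. At an unadjusted p under 0.01 and a 1.3-fold difference, the authors' own columns gave 1992 higher and 2536 lower probe sets for Ent against PBS and 90 and 97 for Lcn2 against PBS. The other sheets of the workbook repeat parts of the main sheet and were left out.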

Results

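Transcripts were measured in A549 cells, an established human lung line that serves as a model of the surfactant-making type II pneumocyte, after exposure to lipocalin 2 (Lcn2), enterobactin (Ent) and iron. Ent is a siderophore, a small molecule with which enteric bacteria take ferric iron from their host, and Lcn2 is a secreted host protein that binds it. Iron (Fe) was given as ferric ammonium citrate, and the vehicle was phosphate-buffered saline (PBS). Experiment 1 held 4 groups of 2 biological replicates: PBS, Lcn2 at 25 µM, Lcn2 with 50 µM Ent (Lcn2+Ent), and Lcn2 with 50 µM Ent and 50 µM iron (Lcn2+Ent+Fe). Experiment 2 held 4 groups of 4 biological replicates: PBS, 50 µM Ent, 50 µM Fe, and both together (Ent+Fe). Each of the 24 arrays gave log2 signals for 29096 probe sets, with array medians between 6.48 and 6.65 and a mean correlation across probe sets with the rest of the own group of 0.995 to 0.998. The number of arrays per group limits the precision of every value. So does background for a gene that lies under the median signal of all probe sets, 6.534 in experiment 1 and 6.556 in experiment 2. CCL20, HK2, ICAM1, IL32, IL6, SNAI2, STC2, TNFAIP3 and TNFRSF9 lay under it in PBS of both experiments. The sizes of their differences from PBS given below are therefore uncertain. A signed value or a rise or fall given for a gene is its log2 difference between the groups compared ± the standard error of the fit, and group levels are mean log2 signals ± SD.

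The comparison of Ent with PBS in experiment 2 asked what the siderophore alone does to these cells, and hypoxia genes were higher throughout. NDRG1, a gene induced by low oxygen, was at 9.60 ± 0.088 in PBS and at 12.06 ± 0.019 with Ent (n = 4 each), a 5.48-fold rise (adjusted p = 2.21e-15). CA9, a carbonic anhydrase that regulates pH, rose from 7.44 ± 0.080 to 10.23 ± 0.10, and VEGFA, the angiogenic growth factor, rose by 1.69 ± 0.050. All 35 measured targets of hypoxia-inducible factor (HIF) were higher, with a median of 1.51 (camera adjusted p = 2.17e-40). Among them PDK1, a kinase that restrains pyruvate oxidation, rose by 2.92 ± 0.055, EGLN3, an oxygen-sensing prolyl hydroxylase, by 2.87 ± 0.055, ANGPTL4, an inhibitor of lipoprotein lipase, by 3.32 ± 0.096, and the secreted peptide gene ADM by 1.26 ± 0.059. HIF1A, which encodes the oxygen-regulated subunit itself, fell by 0.51 ± 0.057. Of the 17 glycolysis genes 15 were higher and 1 lower (median 0.63, adjusted p = 6.14e-11). ALDOC rose by 3.12 ± 0.051, HK2, the first enzyme of the pathway, by 2.76 ± 0.12, and PGK1 by 0.95 ± 0.052. Genes of the mitochondrial respiratory chain moved the other way: of 34, 23 were lower and 1 higher (median -0.20, adjusted p = 1.99e-07). Cholesterol synthesis genes were mostly higher, 17 of 22 against 2 lower (median 0.33, adjusted p = 6.18e-08). The sterol carrier gene STARD4 rose by 1.18 ± 0.059. Of 13 metallothionein and zinc transport genes 10 were higher (median 0.44, adjusted p = 3.17e-06). MT1X rose by 1.22 ± 0.044. When adjusted over the list alone, the counts were the same, except 24 lower for the respiratory chain and 11 higher for metallothioneins.

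Ent also lowered genes of the cell cycle and raised targets of p53, the DNA damage response factor. PLK1, a mitotic kinase, went from 11.14 ± 0.019 to 8.56 ± 0.005, a difference of -2.58 ± 0.068. CCNB1 (cyclin B1) fell by 2.11 ± 0.071, and AURKA, a spindle kinase, was at -1.98 ± 0.072. All 25 measured mitosis genes were lower (median -1.44, adjusted p = 8.29e-31), and so were 28 of 30 DNA replication genes (median -0.80, adjusted p = 8.81e-24). POLE2, a subunit of a replicative DNA polymerase, differed by -1.58 ± 0.063 and the helicase subunit gene MCM6 by -1.38 ± 0.053. All 23 p53 targets were higher (median 1.33, adjusted p = 2.97e-23). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 8.63 ± 0.099 to 10.28 ± 0.11, GADD45A, a growth arrest gene, by 2.34 ± 0.13, the antiproliferative gene BTG2 by 2.09 ± 0.11, and GDF15, a secreted stress cytokine, by 2.05 ± 0.070. The stress factor gene DDIT3 rose by 3.02 ± 0.088 in an amino acid response list in which 13 of 25 genes were higher and 4 lower (median 0.26, adjusted p = 0.00552, and adjusted p = 0.373 with an estimated correlation). Apoptosis genes of the BCL2 and caspase families counted 9 higher and 3 lower of 16 (median 0.23, adjusted p = 0.0452, and adjusted p = 0.0809 with an estimated correlation), with PMAIP1, a promoter of cell death, up by 1.40 ± 0.077. Autophagy genes counted 8 higher and 1 lower of 16 (median 0.16, adjusted p = 0.016, and adjusted p = 0.101 with an estimated correlation). GABARAPL1 rose by 1.16 ± 0.080. All 12 heat shock genes were lower (median -0.42, adjusted p = 1.64e-09), with the mitochondrial chaperonin gene HSPE1 at -0.86 ± 0.063. Ribosome biogenesis genes counted 16 lower and 2 higher of 23 (median -0.45, adjusted p = 1.6e-07, and adjusted p = 0.0595 with an estimated correlation). Targets of the oxidative stress factor NRF2 counted 13 lower and 1 higher of 20 (median -0.16, adjusted p = 0.000645, and adjusted p = 0.0809 with an estimated correlation). The unfolded protein list, with 3 higher and 6 lower of 16, did not pass (median -0.11, adjusted p = 0.464). The counts adjusted over the list alone were the same, except 5 lower in the amino acid response, 2 lower in autophagy, 3 higher in ribosome biogenesis, and 2 higher and 14 lower among NRF2 targets.

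With Ent, 15 of 19 NF-κB feedback genes were higher (median 0.52, adjusted p = 1.64e-09). That list holds genes by which this inflammatory factor is itself regulated, and others such as the adhesion molecule gene ICAM1. TNFAIP3, a deubiquitinase that limits NF-κB, rose by 1.73 ± 0.081, its partner TNIP1 by 1.39 ± 0.065, and the inhibitor of apoptosis gene BIRC3 by 1.41 ± 0.15. Cytokine and chemokine genes went both ways, 7 higher and 3 lower of 26 (median 0.064, adjusted p = 0.0998). CXCL8, a neutrophil chemokine, rose by 2.10 ± 0.15, the monocyte chemokine CCL2 by 1.23 ± 0.13 and CCL20, which attracts lymphocytes and dendritic cells, by 0.88 ± 0.083. The signal of CCL20 was under the median of all probe sets in both groups, 4.56 ± 0.12 in PBS and 5.44 ± 0.12 with Ent, so its rise lies near background. Another neutrophil chemokine gene, CXCL2, fell by 0.89 ± 0.056, and IL6, at 4.82 ± 0.18 in PBS and as near background, did not pass at -0.035 ± 0.078 (adjusted p = 0.785). Iron handling genes were divided, 9 higher and 11 lower of 34 (median -0.018, adjusted p = 0.621). TFRC, the transferrin receptor that imports iron, rose by 0.94 ± 0.045, and CP, a ferroxidase, by 1.73 ± 0.14. SLC40A1, the iron exporter ferroportin, fell by 0.97 ± 0.068, and SLC11A2, a divalent metal transporter, fell by 0.35 ± 0.062. The metalloreductase family gene STEAP1 and the ferritin light chain gene FTL were lower too, at -1.01 ± 0.090 and -0.28 ± 0.047. FTH1 (ferritin heavy chain) at -0.008 ± 0.043 (adjusted p = 0.913) and HMOX1 (heme oxygenase) at -0.098 ± 0.075 (0.361) did not pass. Nor did LCN2 at 0.12 ± 0.074 (0.262) and the Lcn2 receptor gene SLC22A17 at -0.080 ± 0.062 (0.367). Iron-sulfur cluster assembly genes counted 10 lower and 4 higher of 24 (median -0.14, adjusted p = 0.037, and adjusted p = 0.148 with an estimated correlation), with FDXR, an electron donor that is also a p53 target, up by 1.71 ± 0.092. Matrix and mesenchymal genes counted 12 higher and 3 lower of 21 (median 0.16, adjusted p = 0.00168, and adjusted p = 0.148 with an estimated correlation). The transcriptional repressor gene SNAI2 rose by 2.41 ± 0.13. Type II pneumocyte genes counted 6 higher and 2 lower of 17 (median 0.13, adjusted p = 0.00552, and adjusted p = 0.0598 with an estimated correlation), with PLIN2, a lipid droplet coat protein, up by 1.91 ± 0.059. Interferon response genes (4 higher, 8 lower of 25, adjusted p = 0.0819) and epithelial defence genes (2 higher, 1 lower of 22, adjusted p = 0.593) did not pass as lists. OAS1, an antiviral enzyme, fell by 1.21 ± 0.096. Markers of cell types that the culture should lack did not pass: leukocytes 4 higher of 15 (median 0.096, adjusted p = 0.0561), fibroblasts 2 lower of 10 (0.593), endothelium 1 higher of 9 (0.773), and airway epithelium 1 higher and 2 lower of 11 (0.773). For airway epithelium the median was 0.036 while the mean was -0.071 and the test pointed down. Adjusted over the list alone, the counts were 12 higher and 12 lower for iron handling, 8 higher for cytokines, 11 lower for iron-sulfur assembly, 4 lower for matrix genes and 1 lower for fibroblasts, and otherwise the same.

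In all, limma called 10265 of 29096 probe sets between Ent and PBS at an adjusted p under 0.05, 4757 higher and 5508 lower, with 607 at least 2-fold apart. Beyond the lists, H2BC14, a core histone gene, differed by -4.25 ± 0.14, H1-5, a linker histone gene, by -3.35 ± 0.15, CPS1, an enzyme of ammonia disposal, by -2.48 ± 0.12, and the phosphodiesterase gene PDE3A by -2.46 ± 0.084.

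**Figure D1:**
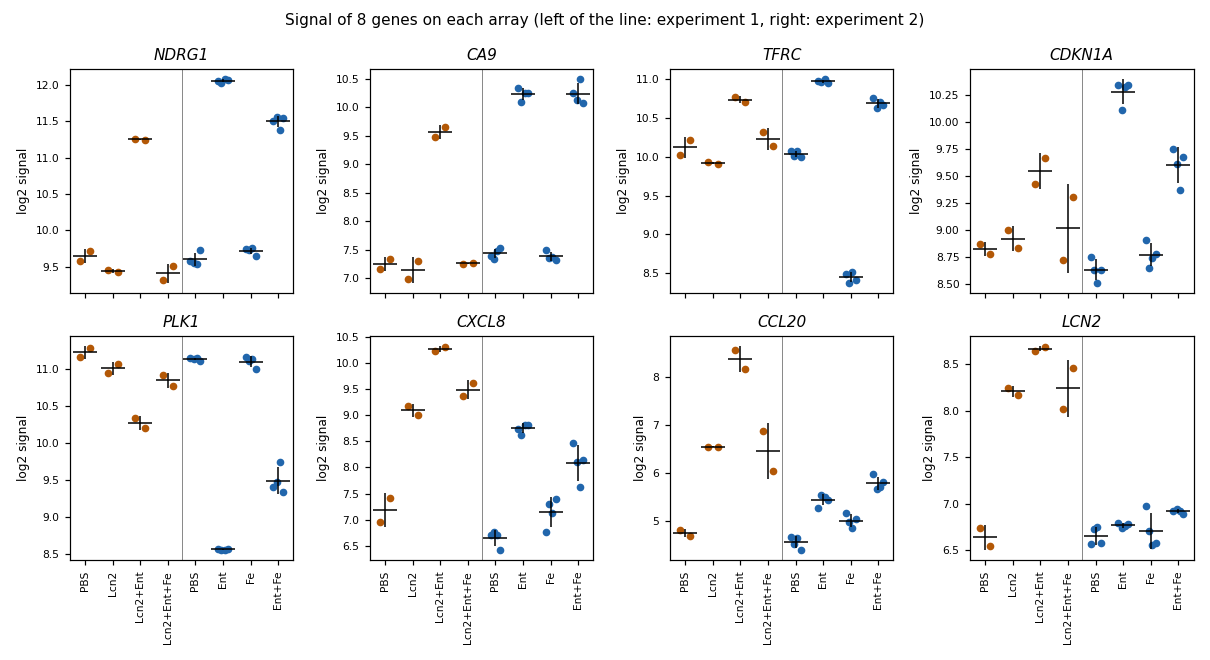
Log2 signal of NDRG1, CA9, TFRC, CDKN1A, PLK1, CXCL8, CCL20 and LCN2 on each of the 24 arrays (points), by group, with bars at the group mean ± SD. NDRG1 was at 9.60 ± 0.088 in PBS, 12.06 ± 0.019 with Ent and 11.50 ± 0.081 with Ent+Fe in experiment 2, and at 11.25 ± 0.009 with Lcn2+Ent and 9.41 ± 0.13 with Lcn2+Ent+Fe in experiment 1.

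Iron alone, compared with PBS in experiment 2, gave far smaller differences, and TFRC showed the largest. TFRC, the transferrin receptor gene, fell from 10.04 ± 0.041 to 8.45 ± 0.064 (n = 4 each), by 1.59 ± 0.045 (adjusted p = 1.44e-12), and HMOX1, heme oxygenase, rose by 0.55 ± 0.075. DNA replication genes were lower, 16 of 30 (median -0.25, camera adjusted p = 1.51e-39). CDC6, a loader of the replicative helicase, differed by -0.44 ± 0.052 and MCM10, an initiation factor, by -0.39 ± 0.050. Cholesterol synthesis genes were higher, 8 of 22 (median 0.19, adjusted p = 5.75e-23). INSIG1, a sterol-regulated anchor protein, rose by 0.43 ± 0.050, and the enzyme genes MVD by 0.32 ± 0.052 and LSS by 0.31 ± 0.050. NF-κB feedback genes were higher, 4 of 19 (median 0.14, adjusted p = 9.14e-09), and so were autophagy genes, 4 of 16 (adjusted p = 1.77e-06). RELB, an NF-κB subunit, rose by 0.29 ± 0.049 and the cargo receptor gene SQSTM1 by 0.25 ± 0.047. Ribosome biogenesis genes were lower, 3 of 23 (median -0.13, adjusted p = 4.23e-13). Of the stress genes, GDF15 rose by 0.50 ± 0.070, TRIB3, a pseudokinase, by 0.60 ± 0.065 and DDIT3 by 0.57 ± 0.088, and PLIN2 rose by 0.60 ± 0.059. Hypoxia genes went both ways: 2 were higher and 2 lower of 35 (median 0.022, adjusted p = 0.306). EGLN3 fell by 0.39 ± 0.055, and AK4, a mitochondrial adenylate kinase, fell by 0.42 ± 0.060. NDRG1 at 0.12 ± 0.052 (adjusted p = 0.406), CA9 at -0.054 ± 0.079 (0.902) and VEGFA at 0.083 ± 0.050 (0.628) did not pass. Iron handling genes counted 3 higher and 2 lower of 34 (adjusted p = 0.918). Among the largest other rises were those of NEU1, a lysosomal sialidase, at 0.75 ± 0.054, RRAGD, a GTPase of lysosomal nutrient sensing, at 0.67 ± 0.087, ACSS2, an acetyl-CoA synthetase, at 0.71 ± 0.056, and MCTP1 at 0.94 ± 0.092. Among the largest other falls were those of ST8SIA4, a sialyltransferase, at -0.72 ± 0.095, NTRK3, a neurotrophin receptor, at -0.63 ± 0.11, and the water channel gene AQP3 at -0.55 ± 0.081. CXCL8 did not pass at 0.50 ± 0.15 (adjusted p = 0.133). When adjusted over the list alone, the counts were 28 lower for DNA replication, 18 higher for cholesterol synthesis, 7 for NF-κB feedback and 7 for autophagy, 9 lower for ribosome biogenesis, 3 higher and 2 lower for hypoxia, and 4 higher and 3 lower for iron handling. Limma called 446 probe sets, 267 higher and 179 lower, and 1 was at least 2-fold apart. The count was 269, 228 and 204 without PBS replicates 1, 2 and 3, and 279, 233 and 286 without Fe replicates 1, 2 and 4.

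Given together with iron, Ent still raised hypoxia genes over PBS. CA9 was at 10.24 ± 0.18 in Ent+Fe (n = 4), 2.80 ± 0.079 above PBS, and NDRG1 rose by 1.90 ± 0.052 and VEGFA by 1.20 ± 0.050. Of 35 HIF targets 34 were higher (median 1.10, camera adjusted p = 2.05e-40). PDK1 rose by 2.59 ± 0.055, ANGPTL4 by 2.48 ± 0.096, the glycoprotein hormone gene STC2 by 2.32 ± 0.075 and EGLN3 by 2.07 ± 0.055. Glycolysis genes counted 15 higher and 1 lower of 17 (median 0.52, adjusted p = 1.41e-11). ALDOC rose by 2.89 ± 0.051. Mitosis genes were lower, 25 of 25 (median -0.85, adjusted p = 3.01e-32). PLK1 differed by -1.65 ± 0.068 and CENPE, a kinetochore motor, by -1.78 ± 0.13. DNA replication genes counted 24 lower and 1 higher of 30 (median -0.30, adjusted p = 9.77e-12). Targets of p53 were higher, 19 of 23 (median 0.55, adjusted p = 6.72e-12, and adjusted p = 0.12 with an estimated correlation). CDKN1A rose by 0.97 ± 0.082 and GDF15 by 1.78 ± 0.070. Genes of NF-κB feedback were higher, 17 of 19 (median 0.52, adjusted p = 6.99e-11). Cytokine genes counted 7 higher and 2 lower of 26 (adjusted p = 0.0434, and adjusted p = 0.173 with an estimated correlation). CXCL8 rose by 1.44 ± 0.15, CCL2 by 1.14 ± 0.13, the cytokine gene LIF by 1.01 ± 0.078 and CCL20, again under the median of all probe sets at 5.79 ± 0.14, by 1.23 ± 0.083. All 22 cholesterol synthesis genes were higher (median 0.33, adjusted p = 4e-13). Leukocyte markers were higher, 7 of 15 (median 0.21, adjusted p = 0.00594, and adjusted p = 0.24 with an estimated correlation), among them CD68, a lysosomal glycoprotein of macrophages that other cells also make, at 0.61 ± 0.063. TFRC stayed above PBS at 0.65 ± 0.045 and SLC40A1 below it at -0.72 ± 0.068. The counts adjusted over the list alone were the same, except 20 higher for p53 and 2 higher for DNA replication. Limma called 10414 probe sets, 5209 higher and 5205 lower, with 152 at least 2-fold apart. That even balance turned either way with single arrays left out, from 3439 higher and 4295 lower without Ent+Fe replicate 2 to 6384 and 5647 without Ent+Fe replicate 1. On the second principal component of experiment 2 (16.45% of the variance), Ent+Fe replicates 2 and 3 lay at 30.17 and 28.99 and replicates 1 and 4 at -1.42 and 6.64, so every Ent+Fe value averages over arrays that lie apart. Ent+Fe arrays correlated with the rest of their group at 0.9948 to 0.9964, against 0.9969 to 0.9981 in the other groups of experiment 2. The standard errors and calls pool the spread of all these groups, so they can overstate the precision of Ent+Fe values. Without replicates 2 and 3 together, a choice made after the data were seen, the count was 6765.

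Against Ent alone, Ent+Fe lowered hypoxia and p53 genes and raised cell cycle genes, with CA9 near its level in Ent. NDRG1 fell by 0.56 ± 0.052 and VEGFA by 0.49 ± 0.050 in Ent+Fe (n = 4 each), and CA9 had a difference of 0.005 ± 0.079 (adjusted p = 0.973). HIF targets counted 28 lower and 1 higher of 35 (median -0.42, camera adjusted p = 3.12e-24). HK2, of the glycolysis list, differed by -1.13 ± 0.12. Targets of p53 were lower, 22 of 23 (median -0.73, adjusted p = 1.69e-26). GADD45A differed by -1.71 ± 0.13, BTG2 by -1.39 ± 0.11 and CDKN1A by -0.68 ± 0.082. DNA replication genes were higher, 28 of 30 (median 0.46, adjusted p = 1.69e-26). POLE2 rose by 0.86 ± 0.063. Mitosis genes counted 19 higher and 1 lower of 25 (median 0.43, adjusted p = 2.08e-13). PLK1 rose by 0.93 ± 0.068. TFRC fell by 0.28 ± 0.045. TNFAIP3 differed by -0.98 ± 0.081, SNAI2 by -1.83 ± 0.13 and ANKRD1, an ankyrin repeat gene, by -1.74 ± 0.18. The histone gene H2BC14 rose by 2.66 ± 0.14. NF-κB feedback genes, 5 of 19 lower, did not pass as a list (adjusted p = 0.0527). Adjusted over the list alone, the counts were 31 lower and 1 higher for HIF targets, 29 higher for DNA replication, 20 higher and 2 lower for mitosis, 6 lower for NF-κB feedback, and the same for p53. Limma called 5864 probe sets, 2733 higher and 3131 lower. The 2 arrays apart on the second component belong to the Ent+Fe group here too, and without both the count was 3844, with the balance turned (1942 higher, 1902 lower).

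The interaction of Ent with Fe asked whether iron changed the effect of Ent, and a positive value means that Ent raised a gene more, or lowered it less, with iron than without. It was 1.31 ± 0.064 for TFRC (adjusted p = 6.66e-09), -0.68 ± 0.073 for NDRG1 and -0.58 ± 0.071 for VEGFA (4 arrays in each of the 4 groups). HIF targets were lower in it, 27 of 35 (median -0.46, camera adjusted p = 5.83e-21), as were p53 targets, 22 of 23 (median -0.82, adjusted p = 2.08e-26). CDKN1A had an interaction of -0.82 ± 0.12. DNA replication genes were higher, 29 of 30 (median 0.70, adjusted p = 4.37e-40). MCM10 had an interaction of 1.13 ± 0.071. Mitosis genes counted 19 higher and 1 lower of 25 (median 0.47, adjusted p = 3.23e-16). Genes of NF-κB feedback were lower, 6 of 19 (median -0.15, adjusted p = 1.61e-05). TNFAIP3 had an interaction of -1.16 ± 0.12, CXCL8 of -1.16 ± 0.21, DDIT3 of -1.18 ± 0.13, PLIN2 of -1.11 ± 0.083 and HMOX1 of -0.70 ± 0.11. When adjusted over the list alone, the counts were 28 lower and 2 higher for HIF targets, 30 higher for DNA replication, and the same for p53, mitosis and NF-κB feedback. Limma called 4036 probe sets, 1861 higher and 2175 lower. Without Ent+Fe replicates 2 and 3 together it called 3648, with the balance turned (1861 higher, 1787 lower).

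Ent and Ent+Fe shared much of their difference from PBS. Of the probe sets called in both, 6707 in number, 6640 went the same way, among them PDK1, EGLN3, ALDOC and PLK1. Of these 2646 were higher and 3994 lower in both, against 851.6 and 985.3 if the calls were independent. The correlation was r = 0.801 across probe sets, which are not independent replicates. The same PBS arrays enter both differences, and groups simulated without any change gave r = 0.5 and a covariance of 0.00358, against 0.0689 here. With different PBS arrays for each difference, r was 0.687 to 0.793 and 4427 to 4730 probe sets were called in both over the 6 ways of splitting the PBS group. Those differences share no array, so the simulated r is no reference for them. The simulations drew each probe set independently, so they hold no variation that the probe sets of an array share.

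**Figure D2:**
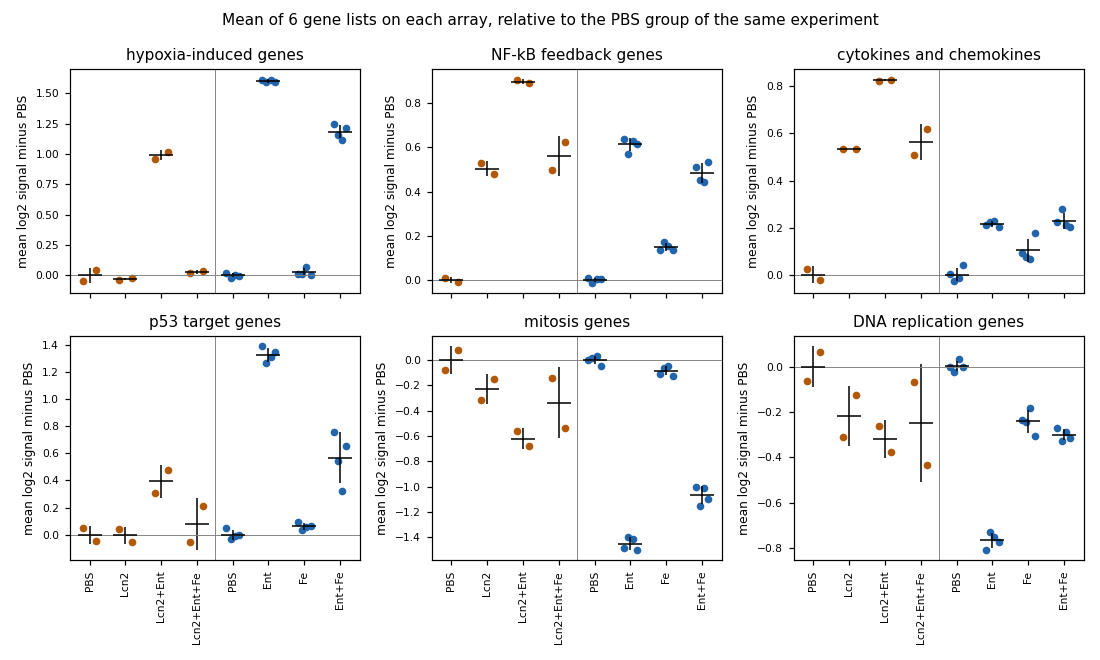
Mean log2 signal of the members of 6 gene lists on each of the 24 arrays (points), minus the mean of the PBS arrays of the same experiment. Hypoxia genes were at 1.60 ± 0.013 with Ent and 1.18 ± 0.057 with Ent+Fe in experiment 2, and at 0.99 ± 0.042 with Lcn2+Ent and 0.026 ± 0.015 with Lcn2+Ent+Fe in experiment 1 (mean ± SD over arrays).

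Lcn2 alone, compared with PBS in experiment 1, raised chemokine and NF-κB genes, with no call among hypoxia genes. The neutrophil chemokine genes CXCL1 and CXCL8 rose by 2.11 ± 0.12 and 1.92 ± 0.15 (n = 2 each), TNFAIP3 by 1.73 ± 0.068 (adjusted p = 4.25e-05), C3, the central complement component, by 2.04 ± 0.086, SOD2, a mitochondrial superoxide dismutase, by 1.73 ± 0.086, and the cells' own LCN2 gene by 1.57 ± 0.13. Cytokine genes were higher, 6 of 26 (median 0.29, camera adjusted p = 7.11e-09, and adjusted p = 0.0973 with an estimated correlation). IL32 rose by 1.41 ± 0.080, CCL20 by 1.79 ± 0.23 and IL6 by 0.67 ± 0.099. CCL20, at 4.75 ± 0.080 in PBS and 6.54 ± 0.011 with Lcn2, and IL6, at 4.66 ± 0.10 and 5.33 ± 0.13, started near background. NF-κB feedback genes were higher, 5 of 19 (median 0.33, adjusted p = 5.47e-13, and adjusted p = 0.0973 with an estimated correlation), with the adhesion molecule gene ICAM1 at 1.03 ± 0.069. Epithelial defence genes were higher too, 3 of 22 (median 0.16, adjusted p = 1.9e-06, and adjusted p = 0.374 with an estimated correlation), with complement factor B (CFB) at 1.08 ± 0.11. CYP1B1, a cytochrome P450, rose by 2.02 ± 0.12. Lower were NR4A1 and NR4A2, nuclear receptors of the immediate early response, at -1.35 ± 0.14 and -1.46 ± 0.20, OAS1 at -1.01 ± 0.11 and HAS2, a hyaluronan synthase, at -1.07 ± 0.092. By limma 0 of 35 HIF targets were called, with 5 higher and 5 lower at an unadjusted p under 0.05 (median -0.044, adjusted p = 0.162). NDRG1 at -0.21 ± 0.083 (adjusted p = 0.27), CA9 at -0.11 ± 0.11 (0.665) and TFRC at -0.21 ± 0.091 (0.308) did not pass. Mitosis genes had a median of -0.22 (adjusted p = 4.67e-08, and adjusted p = 0.507 with an estimated correlation), with 0 of 25 called by limma and 6 lower at an unadjusted p under 0.05. Leukocyte markers (median 0.13, adjusted p = 0.0477, and adjusted p = 0.377 with an estimated correlation) and endothelial markers (median 0.19, adjusted p = 0.0325, and adjusted p = 0.507 with an estimated correlation) gave 0 calls by limma, with 3 of 15 higher, and 4 higher and 1 lower of 9, at an unadjusted p under 0.05. The counts adjusted over the list alone were 13 higher and 1 lower for cytokines, 12 higher for NF-κB feedback, 8 higher for epithelial defence, 1 lower for hypoxia and the same for mitosis and leukocyte markers, with 1 higher for endothelium. Limma called 70 probe sets, 32 higher and 38 lower, a balance that turned with every array left out. The count was 18 (15 higher, 3 lower) and 15 (14 and 1) without PBS replicates 1 and 2 and 13 without either Lcn2 replicate (11 and 2 without replicate 1, 12 and 1 without replicate 2), 36 with a replicate block (23 and 13), and 2 without variance moderation. Of the 23 genes that the naming rule gave and that passed, 9 kept their call whichever array was left out, and these include every passing gene with a value here except CCL20, IL6, CFB, NR4A1, NR4A2, OAS1 and HAS2. Calls were kept by 13 and 11 of the 23 without PBS replicates 1 and 2, and by 10 without either Lcn2 replicate.

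Lcn2 together with Ent, compared with PBS in experiment 1, raised both the hypoxia genes and the chemokine genes. CA9 rose from 7.25 ± 0.12 to 9.56 ± 0.12 and NDRG1 from 9.65 ± 0.092 to 11.25 ± 0.009 (n = 2 each, adjusted p = 3.81e-05 for NDRG1). CCL20 rose by 3.60 ± 0.23, CXCL8 by 3.09 ± 0.15 and IL6 by 1.42 ± 0.099. In PBS CCL20, at 4.75 ± 0.080, was near background, so the size of its rise to 8.35 ± 0.27 is uncertain, and IL6 stayed under the median of all probe sets, at 6.08 ± 0.089 with Lcn2+Ent. HIF targets were higher, 30 of 35 (median 0.83, camera adjusted p = 3.9e-42). PDK1 rose by 2.37 ± 0.13, STC2 by 2.23 ± 0.19 and VEGFA by 0.68 ± 0.091. Glycolysis genes counted 10 higher and 1 lower of 17 (median 0.46, adjusted p = 3.8e-13). ALDOC rose by 2.73 ± 0.082. Cytokine genes counted 12 higher of 26 (median 0.40, adjusted p = 9.97e-15) and NF-κB feedback genes 13 of 19 (median 0.80, adjusted p = 1.06e-20). LCN2 rose by 2.03 ± 0.13, C3 by 2.01 ± 0.086, CYP1B1 by 2.97 ± 0.12 and TNFRSF9, a receptor of the tumor necrosis factor family, by 2.48 ± 0.25. Cholesterol synthesis genes were higher, 18 of 22 (median 0.49, adjusted p = 7.24e-22, and adjusted p = 0.0563 with an estimated correlation). INSIG1 rose by 1.17 ± 0.080. Mitosis genes were lower, 14 of 25 (median -0.55, adjusted p = 2.9e-18, and adjusted p = 0.203 with an estimated correlation). PLK1 differed by -0.95 ± 0.088 and CDC20, an activator of the anaphase-promoting complex, by -0.99 ± 0.078. Targets of p53 were higher, 9 of 23 (median 0.40, adjusted p = 1.59e-10, and adjusted p = 0.238 with an estimated correlation). CDKN1A rose by 0.72 ± 0.17, and TFRC rose by 0.61 ± 0.091. Adjusted over the list alone, the counts were 34 higher and 1 lower for HIF targets, 12 higher and 1 lower for glycolysis, 16 higher for cytokines, 14 for NF-κB feedback, 21 for cholesterol and 14 for p53, and 20 lower for mitosis. Limma called 1739 probe sets, 863 higher and 876 lower. Without PBS replicates 1 and 2 and Lcn2+Ent replicates 1 and 2 it called 545, 504, 544 and 461 (278 without variance moderation), of which 303, 338, 359 and 265 were higher, more than were lower each time. Of the 97 genes that the rule gave and that passed, 70, 64, 68 and 64 kept their call without those arrays in the same order. Of the genes with a value here TFRC and CDKN1A lost it without at least 1 of them.

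Against Lcn2 alone, a comparison that asks what Ent adds when Lcn2 is present, Lcn2+Ent raised hypoxia genes and the iron importer gene TFRC. CA9 was higher by 2.42 ± 0.11, NDRG1 by 1.81 ± 0.083 (adjusted p = 5.13e-05), PDK1 by 2.35 ± 0.13 and P4HA1, a collagen prolyl hydroxylase, by 1.97 ± 0.078 (n = 2 each). HIF targets counted 29 higher of 35 (median 0.96, camera adjusted p = 5.11e-57) and glycolysis genes 10 of 17 (median 0.51, adjusted p = 6.57e-19). NF-κB feedback genes were higher, 8 of 19 (median 0.35, adjusted p = 4.03e-13). BIRC3 rose by 1.13 ± 0.099. Cytokine genes were higher too, 5 of 26 (adjusted p = 1.58e-07, and adjusted p = 0.0514 with an estimated correlation). CCL20 rose by 1.81 ± 0.23, CXCL8 by 1.17 ± 0.15 and IL6, under the median of all probe sets in both groups, by 0.75 ± 0.099. TFRC rose by 0.81 ± 0.091, and LCN2 did not pass at 0.46 ± 0.13 (adjusted p = 0.128). When adjusted over the list alone, the counts were 34 higher for HIF targets, 14 higher and 1 lower for glycolysis, 12 higher for NF-κB feedback, and 10 higher and 1 lower for cytokines. Limma called 655 probe sets, 519 higher and 136 lower, and 176 and 125 without Lcn2 replicates 1 and 2 and 175 and 89 without Lcn2+Ent replicates 1 and 2 (38 without variance moderation). Of the 63 genes that the rule gave and that passed, 33, 27, 30 and 24 kept their call without those arrays in the same order. Of the genes with a value here CCL20, CXCL8 and IL6 lost it without at least 1 of them.

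With iron added to Lcn2 and Ent, hypoxia genes were near their PBS level while chemokine genes stayed above it. CA9 was at 7.26 ± 0.014 against 7.25 ± 0.12 in PBS (n = 2 each). The differences of CA9 at 0.007 ± 0.11 (adjusted p = 0.988), VEGFA at 0.011 ± 0.091 (0.977), NDRG1 at -0.24 ± 0.083 (0.307) and TFRC at 0.11 ± 0.091 (0.699) did not pass. CXCL8 rose by 2.32 ± 0.15, CXCL1 by 2.21 ± 0.12, C3 by 2.09 ± 0.086, TNFAIP3 by 1.86 ± 0.068 and LCN2 by 1.61 ± 0.13 over PBS. Of 35 HIF targets 2 were lower (median 0.057, camera adjusted p = 0.497), AK4, an adenylate kinase, at -0.71 ± 0.11 and EGLN1, an oxygen-sensing prolyl hydroxylase, at -0.47 ± 0.075. Glycolysis genes gave 0 calls of 17 by limma, with 1 at an unadjusted p under 0.05 (adjusted p = 0.84). Cytokine genes were higher, 8 of 26 (median 0.29, adjusted p = 9.09e-12, and adjusted p = 0.0592 with an estimated correlation). NF-κB feedback genes were higher too, 7 of 19 (median 0.38, adjusted p = 6.27e-18, and adjusted p = 0.0592 with an estimated correlation). CYP1B1 rose by 2.86 ± 0.12, and NR4A1 and NR4A2 were lower, at -1.97 ± 0.14 and -2.13 ± 0.20. The counts adjusted over the list alone were 1 higher and 2 lower for HIF targets, 13 higher and 1 lower for cytokines, 12 higher for NF-κB feedback and the same for glycolysis. Limma called 163 probe sets, 65 higher and 98 lower, and 41 and 36 without PBS replicates 1 and 2 and 264 and 61 without Lcn2+Ent+Fe replicates 1 and 2 (1 without variance moderation). Without either PBS replicate or Lcn2+Ent+Fe replicate 2 the higher were the more numerous, at 22, 24 and 34. Of the 28 genes that the rule gave and that passed, 15, 14, 26 and 17 kept their call without those arrays in the same order. Of the genes with a value here AK4 and EGLN1 lost it without at least 1 of them.

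Set directly against Lcn2+Ent, Lcn2+Ent+Fe lowered the hypoxia genes. CA9 fell by 2.31 ± 0.11 (n = 2 each) and NDRG1 fell by 1.84 ± 0.083 (adjusted p = 7.44e-05). PDK1 differed by -2.23 ± 0.13 and ALDOC by -2.52 ± 0.082. HIF targets counted 27 lower of 35 (median -0.85, camera adjusted p = 7.55e-57), and glycolysis genes 9 lower of 17 (median -0.39, adjusted p = 3.98e-18, and adjusted p = 0.0536 with an estimated correlation). With an estimated correlation HIF targets were the only list that kept its call in this comparison, and 16 lists lost it. NF-κB feedback genes were lower, 6 of 19 (median -0.29, adjusted p = 2.94e-11, and adjusted p = 0.0536 with an estimated correlation). ICAM1 differed by -0.80 ± 0.069. Cytokine genes were lower too, 4 of 26 (adjusted p = 9.71e-07, and adjusted p = 0.0638 with an estimated correlation). CCL20, which ended under the median of all probe sets at 6.45 ± 0.58, differed by -1.90 ± 0.23 and CXCL8 by -0.78 ± 0.15. TFRC fell by 0.50 ± 0.091, and LCN2 did not pass at -0.43 ± 0.13 (adjusted p = 0.16). Adjusted over the list alone, the counts were 34 lower for HIF targets, 12 lower and 1 higher for glycolysis, 12 lower for NF-κB feedback and 9 lower for cytokines. Limma called 476 probe sets, 131 higher and 345 lower, and 114 and 66 without Lcn2+Ent replicates 1 and 2 and 178 without Lcn2+Ent+Fe replicate 1 (38 without variance moderation). Of the 56 genes that the rule gave and that passed, 24, 18, 35 and 43 kept their call without Lcn2+Ent replicates 1 and 2 and Lcn2+Ent+Fe replicates 1 and 2. Of the genes with a value here CCL20, CXCL8 and TFRC lost it without at least 1 of them.

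The 3 groups that received Lcn2 had differences from PBS in common. Between Lcn2 and Lcn2+Ent+Fe 60 probe sets were called in both, all in the same direction (26 higher, 34 lower, each against 0.1 if independent). Between Lcn2 and Lcn2+Ent 58 were (27 higher, 31 lower, against 0.9 and 1.1). CXCL1, CXCL8, C3, SOD2 and TNFAIP3 were among those higher in all. The PBS arrays are shared here. Across probe sets, which are not independent replicates, r was 0.748 for Lcn2 with Lcn2+Ent+Fe and 0.572 for Lcn2 with Lcn2+Ent, where groups simulated without any change gave 0.5 and 0.499. The covariances were 0.0189 and 0.0194 against simulated 0.00598 and 0.00599, and no probe set was called in both in any simulation. The simulations drew each probe set independently. They therefore cannot show how far r and the covariance stray when the probe sets of an array vary together. With 1 PBS array for each difference, a choice made after the data were seen, r was 0.386 and 0.497 for the 2 ways with Lcn2+Ent+Fe and 0.296 and 0.42 with Lcn2+Ent. These differences share no array, so the simulated 0.5 and 0.499, which hold for shared PBS arrays, are no reference for them. Unchanged groups were not simulated for this split. The probe sets called in both then fell to 15 and 16 with Lcn2+Ent+Fe and to 14 and 17 with Lcn2+Ent, all in the same direction, 13 or 14 of them higher, so the lower calls in common were mostly lost.

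The cross-experiment tests asked whether the effect of Lcn2+Ent differed from that of Ent, and the effect of Lcn2+Ent+Fe from that of Ent+Fe. Each effect was taken over the PBS group of its own experiment. The difference therefore holds what Lcn2 does on its own as well as any change in the response to Ent. CXCL1, C3 and LCN2 were already higher with Lcn2 alone. For Lcn2+Ent minus Ent, CXCL1 was higher by 2.90 ± 0.15, CCL20 by 2.72 ± 0.22 and LCN2 by 1.92 ± 0.15, where CCL20 was near background in both PBS groups. ANGPTL4 differed by -1.99 ± 0.16, GADD45A by -1.94 ± 0.22 and NDRG1 by -0.85 ± 0.092 (n = 2 and n = 4 per group). HIF targets were lower, 25 of 35 (median -0.55, camera adjusted p = 4.85e-30), and p53 targets too, 22 of 23 (median -0.87, adjusted p = 4.85e-30). Mitosis genes were higher, 20 of 25 (median 0.87, adjusted p = 4.15e-30). PLK1 was higher by 1.62 ± 0.12. Cytokine genes counted 8 higher and 1 lower of 26 (median 0.18, adjusted p = 3.37e-09). For Lcn2+Ent+Fe minus Ent+Fe, CA9 differed by -2.79 ± 0.14, PDK1 by -2.45 ± 0.13, NDRG1 by -2.14 ± 0.092 and TFRC by -0.55 ± 0.088. CXCL1 was higher by 2.23 ± 0.15, C3 by 2.03 ± 0.11 and LCN2 by 1.34 ± 0.15. HIF targets were lower, 34 of 35 (median -1.06, adjusted p = 2.01e-61), glycolysis genes too, 12 of 17 (median -0.43, adjusted p = 4.24e-18). Cytokine genes counted 7 higher and 2 lower of 26 (median 0.14, adjusted p = 0.000789). CCL20, near background in both PBS groups, did not pass, with a difference of 0.48 ± 0.22 (adjusted p = 0.191). When adjusted over the list alone, the counts were 30 lower for HIF targets, 23 higher for mitosis, 11 higher and 1 lower for cytokines and the same for p53 without iron, and 35 lower for HIF targets, 12 lower and 1 higher for glycolysis and the same for cytokines with iron. Limma called 2784 probe sets without iron (1514 higher, 1270 lower), and 1638 and 1685 without Exp1 PBS replicate 1 and Lcn2+Ent replicate 1. With iron it called 2767 (1606 higher, 1161 lower), and 1377 and 1464 without Exp1 PBS replicate 1 and Lcn2+Ent+Fe replicate 1. Lcn2 was given in experiment 1 alone, so its effect and any other difference between the experiments cannot be told apart, and the PBS groups of the experiments differed in 1097 probe sets (3.8%).

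Across probe sets, which are not independent replicates, the Lcn2+Ent effect followed the Ent effect with r = 0.667 and a slope of 0.414. Of the probe sets called in both, 1468 of the 1498 went the same way, 704 higher against 141.1 if independent and 764 lower against 165.8. NDRG1, CA9, PDK1 and CXCL8 were higher and PLK1 lower in both. The Lcn2+Ent+Fe effect followed the Ent+Fe effect with r = 0.319 and a slope of 0.199, and 94 of 107 went the same way, 41 higher against 11.6 and 53 lower against 17.5.

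**Figure D3:**
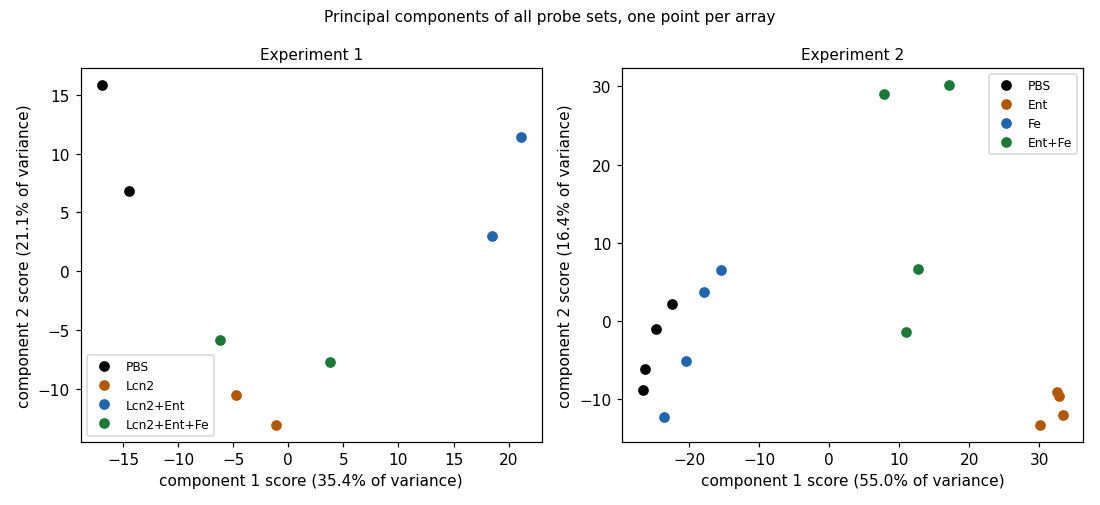
Scores of each array on the first and the second principal component of the log2 signals, computed in each experiment on its own, with the share of variance on the axes. In experiment 2, where the first component holds 54.97% of the variance, the Ent+Fe arrays had scores of 7.84 to 17.07 on it.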

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

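The tests of compressed signal and of the degree of the Ent response on Ent+Fe arrays, of normalization and of TFRC for the hypoxia genes, and of a bacterial product for the Lcn2 genes were chosen only after the result was seen, and the others before it.

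The effect of Ent differed between cells without and with iron in 4036 probe sets by a test of the interaction. The effect of Lcn2+Ent over its own PBS group differed from that of Ent in 2784 probe sets, and the effect of Lcn2+Ent+Fe from that of Ent+Fe in 2767, by tests of the difference across experiments.

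Hypoxia genes were higher in Ent+Fe (median 1.10) and, apart from AK4 and EGLN1, which were lower, gave no call in Lcn2+Ent+Fe (median 0.057), with 6 higher and 4 lower by limma at an unadjusted p under 0.05. A trend with signal level left between the arrays is argued against, since after cyclic loess the median of the difference between the effects was -1.11. The deposited values of all arrays already had nearly the same distribution. Cyclic loess could remove no more than such trends, and other effects of normalization were not tested. One hypothesis is that Ent left unsaturated by iron may still keep iron from the cells when Lcn2 is absent. Ent and iron were given at equal concentrations, and no value here gives how much Ent was left without iron. TFRC, whose transcript is stabilised in iron-poor cells, was above PBS by 0.65 in Ent+Fe, which the hypothesis requires. But TFRC was above PBS in the same groups as the hypoxia genes (Ent, Ent+Fe and Lcn2+Ent). Its rise therefore cannot tell iron kept from the cells apart from another cause that raises both, and the hypothesis stays open. Another difference between the experiments cannot be told apart from Lcn2, which was given in experiment 1 only: the PBS groups differed in 1097 probe sets, 606 higher and 491 lower in experiment 1 (3.8%). That share is under the 5% that was set beforehand as excluding this explanation, but the bound was wrong, because PBS arrays carry no information on preparations such as the Ent lots, which only treated cells received.

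Chemokine and NF-κB feedback genes were higher with Lcn2 alone, 11 members of the lists in all. A trend with signal level left between the arrays is argued against, since 10 of them were still called after cyclic loess. Other effects of normalization were not tested. A response to the Lcn2 protein and a response to a bacterial product carried in its preparation cannot be told apart: 11 were also called in both other groups that received Lcn2, which either explanation requires, and no group received a preparation in which Lcn2 was inactive.

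Ent+Fe replicates 2 and 3 lay at 30.17 and 28.99 on the second component of experiment 2, against -1.42 and 6.64 for replicates 1 and 4. They also had the 2 narrowest interquartile ranges of the 24 arrays (3.18 and 3.24, the others at least 3.30) and the 2 highest medians (6.65 and 6.61), and their deviations from the group correlated with the probe sets' mean level at -0.203 and -0.128, all of which compressed signal would give. The correlation with mean level was -0.129 for Fe replicate 4, so the size in Ent+Fe replicate 3 is not particular to it. As the whole cause it is argued against: cyclic loess brought the ranges of the 16 arrays to between 3.32 and 3.352, and the replicates still lay at 28.44 and 28.6 on the second component, against -0.03 and 7.06, a gap of 0.957 of that before. A part of it by compression stays open. Another degree of the response to Ent also stays undecided and cannot be told apart from other sources, since values went both ways. The deviations correlated across probe sets with the Ent effect at -0.218 for replicate 3 and 0.133 for replicate 2. Arrays that received no Ent reached similar sizes, with Fe replicate 3 at -0.151 and Fe replicate 4 at 0.151. Over PBS, replicates 2 and 3 were below replicates 1 and 4 for the hypoxia list (1.158 and 1.118 against 1.245 and 1.216), p53 targets (0.546 and 0.32 against 0.755 and 0.65) and NF-κB feedback (0.452 and 0.441 against 0.511 and 0.532), while for mitosis genes replicate 2 was the furthest from PBS (-1.155 and -1.015 against -1.003 and -1.099). No other biological explanation was tested, since the labels give no difference between these replicates.

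In experiment 2 no other grouping of the arrays came near the real counts. Ent against PBS called 10265 probe sets and no other of the 35 splits of those arrays more than 0. Ent+Fe against PBS called 10414 (highest other 0), Ent+Fe against Ent 5864 (highest other 0), and Fe against PBS 446 (highest other 1). The interaction gave 4036 (highest other 2 among 100 regroupings). In each, 1 split, the real one, reached the real count, the lowest share such a test can give. The other splits mix arrays of groups that differ, which widens the spread within a group and lowers their counts. They therefore cannot exclude chance. The tests by limma at an unadjusted p under 0.05 gave 12273, 13481, 9260, 3132 and 7203 for the real groups in the same order.

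Within groups of 4 arrays, 1 array stood far from the others for 23 of 484 groups of values tested, where chance gives about 1 in 20, or 24.2. The numbers here are the gap to the nearest other array as a share of the range of the group. For lists they were 0.868 (autophagy) and 0.911 (endothelium) in PBS, 0.84 (apoptosis) in Ent, and 0.896 (hypoxia), 0.911 (unfolded protein) and 0.841 (autophagy) in Fe. In PBS replicate 4 stood apart for CDC6 (0.85), MCTP1 (0.863) and NR4A2 (0.875), and replicate 2 for INSIG1 (0.971). In Ent it was replicate 2 for CDKN1A (0.909) and CDC6 (0.84) and replicate 3 for GADD45A (0.869). In Fe it was replicate 1 for SLC11A2 (0.853), replicate 3 for SOD2 (0.851) and ST8SIA4 (0.83), and replicate 4 for TNIP1 (0.924). In Ent+Fe it was replicate 1 for ALDOC (0.842), replicate 2 for CXCL2 (0.886), replicate 3 for CYP2S1 (0.854), GDF15 (0.841) and NR4A2 (0.867), and replicate 4 for RELB (0.974).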

How the results depend on the processing

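The fit without Ent+Fe replicates 2 and 3 together, the pairs that share no arrays and the use of 1 PBS array per comparison in experiment 1 were chosen only after the data were seen, and the other alternatives before. No called named gene reversed its direction under any alternative. Of the refits, only cyclic loess, array weights and left-out arrays change the log2 difference itself, so the others could not reverse it. Of 988 calls, 625 were kept in every alternative run for them, the 1.5-fold threshold apart, and 363 were lost in at least 1. Kept were 112 of 116 for Ent, 37 of 59 for Fe, 104 of 119 for Ent+Fe, 97 of 121 for Ent+Fe against Ent, 89 of 106 for the interaction, 28 of 97 for Lcn2+Ent, 6 of 63 for Lcn2+Ent against Lcn2, 7 of 56 for Lcn2+Ent+Fe against Lcn2+Ent, 78 of 107 and 65 of 93 for the differences across experiments without and with iron, and 1 of 23 for Lcn2 and 1 of 28 for Lcn2+Ent+Fe, in both cases TNFAIP3. Of 174 calls of lists by camera, 62 were kept with an estimated correlation, 143 with fry, 149 after the low-signal filter and 172 with the replicate block. Signal over background limits which probe sets can be called: the median signal of all probe sets, used as the floor of the low-signal filter, was 6.534 in experiment 1 and 6.556 in experiment 2. Of the genes with a value in the text, CCL20, HK2, ICAM1, IL32, IL6, SNAI2, STC2, TNFAIP3 and TNFRSF9 lay under it in PBS of both experiments, CFB in PBS of experiment 1, RRAGD in PBS of experiment 2, H1-5 and PDE3A with Ent, and CYP1A1 in its mean over each experiment (5.56 and 5.28).

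With each array left out in turn, the number of called probe sets was 9256 to 9850 for Ent, 204 to 344 for Fe, 7734 to 12031 for Ent+Fe, 4718 to 7293 for Ent+Fe against Ent, 3419 to 4703 for the interaction, 13 to 18 for Lcn2, 461 to 545 for Lcn2+Ent, 36 to 264 for Lcn2+Ent+Fe, 89 to 176 for Lcn2+Ent against Lcn2, 66 to 343 for Lcn2+Ent+Fe against Lcn2+Ent, and 1638 to 2669 and 1377 to 3477 for the differences across experiments without and with iron. Where a group of 2 loses an array, the lone array is assumed to vary like the other groups. The single arrays that moved a count by more than 1.5 times are named with their counts beside each comparison. Without Ent+Fe replicates 2 and 3 together, the counts were 6765 for Ent+Fe and 3844 for Ent+Fe against Ent, where fewer arrays enter, and 13 calls of named genes were lost for Ent+Fe, 19 for Ent+Fe against Ent, 13 for the interaction and 9 for the difference across experiments with iron. One of them was the call of LCN2, Ent+Fe vs PBS, at 0.251, which was also lost at 0.264 with 1.5-fold asked as well.

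With at least 1.5-fold asked as well, the counts were 2216 for Ent, 27 for Fe, 856 for Ent+Fe, 591 for Ent+Fe against Ent, 931 for the interaction, 499 for Lcn2+Ent, 101 for Lcn2+Ent+Fe, 236 for Lcn2+Ent against Lcn2, 199 for Lcn2+Ent+Fe against Lcn2+Ent, and 928 and 740 for the differences across experiments without and with iron, since the threshold is stricter. The direction with more calls was not stable in any comparison except Fe, Lcn2+Ent against Lcn2 and Lcn2+Ent+Fe against Lcn2+Ent. With array weights 6558 were higher and 6450 lower for Ent, 6701 and 6027 for Ent+Fe, and 3855 and 3646 for Ent+Fe against Ent. After the low-signal filter 3464 were higher and 4796 lower for Ent+Fe. Without Exp1 PBS replicate 1 there were 803 higher and 835 lower for the difference across experiments without iron and 678 and 699 with iron. For Lcn2, the count was 120 with trend and robust fitting, 2 without variance moderation or with the authors' p-values, 36 with the replicate block and 244 in a fit over all 24 arrays. For Lcn2+Ent it was 278 without moderation or with the authors' p-values and 2643 over 24 arrays. For Lcn2+Ent+Fe it was 291 with trend and robust fitting, 1 without moderation or with the authors' p-values, 102 with the block, 498 over 24 arrays and 45 with only the compared groups. For Lcn2+Ent against Lcn2 it was 1025 after the low-signal filter, 985 with trend and robust fitting, 38 without moderation or with the authors' p-values, and 1372 over 24 arrays. For Lcn2+Ent+Fe against Lcn2+Ent it was 1017 after the filter, 931 with trend and robust fitting, 38 without moderation or with the authors' p-values, 778 with 1 probe set per symbol, 1328 over 24 arrays and 195 with only the compared groups. For Fe it was 746 after the filter, 1158 with array weights and 759 with the authors' p-values, and for Lcn2+Ent minus Ent across experiments 4235 with array weights. Fits without moderation or with fewer groups have fewer degrees of freedom, and the filter and the choice of 1 probe set test fewer, while for the other changes the cause was not tested. The correlation of effects across experiments stayed between 0.664 and 0.742 for Lcn2+Ent with Ent and between 0.292 and 0.392 for Lcn2+Ent+Fe with Ent+Fe. Replicate numbers gave no sign common to all pairs of groups: the residuals of arrays with the same number correlated at -0.366 to 0.311 between groups in experiment 1, and in experiment 2 at -0.247 to 0.075 as means per pair of groups and -0.336 to 0.298 for single pairs of arrays. For pairs of effects without a shared array, Ent+Fe minus Fe followed Ent minus PBS with r = 0.709 across probe sets. Lcn2+Ent+Fe minus Lcn2 had a correlation of r = 0.057 with Lcn2+Ent minus PBS. The 2 values do not measure the same thing, since no group received Lcn2 with Fe alone. The first pair sets Ent with iron against Ent without. The other pair sets Ent and iron together against Lcn2 and Ent together.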

Other observations

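The histone set and the targets of the aryl hydrocarbon receptor were chosen after values were seen, and both receptor tests before their own result was.

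Histone genes that are transcribed with DNA replication, a set outside the fixed lists, were mostly lower with Ent. Of 65 measured, 50 were lower and 2 higher with Ent (median -0.96, limma, n = 4 each), and 52 lower and 1 higher with Ent+Fe (median -0.53). H1-5, a linker histone, fell by 3.35 ± 0.15 with Ent, and H2BC14, a core histone, fell by 4.25 ± 0.14. In experiment 2 iron moved them back in part: Ent+Fe was above Ent for 36 and below it for 6 (median 0.33), with H2BC14 at 2.66 ± 0.14, and the interaction was positive for 34 and negative for 3. In experiment 1 there was little to move back, since few were called lower with Lcn2+Ent. Lcn2+Ent+Fe was above Lcn2+Ent for 1 and below it for 0 (median -0.1, n = 2 each), with 1 higher and 20 lower by limma at an unadjusted p under 0.05. Whether iron acted otherwise with Lcn2 present was not tested for this set. After cyclic loess the counts were 51 lower and 2 higher with Ent, 55 and 1 with Ent+Fe, 36 higher and 6 lower for Ent+Fe against Ent, and 33 and 4 for the interaction. With Fe alone limma called 0 of 65, with 0 higher and 1 lower at an unadjusted p under 0.05. In experiment 1 (n = 2 each), 5 were lower and 2 higher with Lcn2+Ent (median -0.12, with 22 lower and 5 higher at an unadjusted p under 0.05). With Lcn2+Ent+Fe 1 was lower and 0 higher by limma (median -0.27, with 38 lower and 0 higher unadjusted), and with Lcn2 0 were called (median -0.13, with 14 lower and 0 higher unadjusted). The difference of the Lcn2+Ent effect from the Ent effect was positive for 42 and negative for 1 (median 0.88), with H2BC14 at 3.74 ± 0.22. Many of these genes are near copies of each other: 52 have a probe set assigned to 1 gene, of which 38 were lower and 2 higher with Ent.

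CYP1B1, an enzyme that the aryl hydrocarbon receptor induces, rose by 2.02 ± 0.12 with Lcn2 and by 1.36 ± 0.11 with Ent. A hypothesis is that the receptor may be active in these cells, and 7 other known targets were tested. With Ent 3 of the 7 were higher, TIPARP at 2.36 ± 0.086, CYP2S1 at 1.16 ± 0.051 and CYP1A1, near background with a mean signal of 5.28, at 0.33 ± 0.084. This met the prediction of at least 3 that was set beforehand, while 2 were lower, NQO1 at -0.10 ± 0.039 and ALDH3A1 at -0.17 ± 0.056. But Ent called 35.3% of all 29096 probe sets, 4757 of them higher, so 3 of 7 cannot single out the receptor. With Ent+Fe, CYP1B1 rose by 1.93 ± 0.11. TIPARP (2.05 ± 0.086), CYP2S1 (1.09 ± 0.051), CYP1A1 (0.60 ± 0.084) and ALDH3A1 (0.15 ± 0.056) were called higher there. CYP1A2, AHRR and NQO1 did not pass. Ent+Fe called 35.8% of all probe sets, 5209 of them higher, so these calls cannot single it out either. With Lcn2 limma called 0 of the 7, with 1 higher and 1 lower at an unadjusted p under 0.05 and TIPARP at 0.72 ± 0.16 (adjusted p = 0.137), and the hypothesis remains undecided there. At most 1 of 7 was set beforehand as excluding it, but the bound was wrong, because groups of 2 arrays do not give a call for every rise of this size. In the self-test of groups of 2, run for Lcn2+Ent+Fe against PBS, 31 of 50 changes of 1.5-fold and 46 of 50 of 2-fold were called. CYP1A1 did not pass by limma at 0.61 ± 0.23 with Lcn2+Ent (adjusted p = 0.163). With Lcn2+Ent TIPARP was called at 2.06 ± 0.16, while CYP2S1 did not pass by limma at 0.052 ± 0.066 (adjusted p = 0.735). TIPARP was called at 1.35 ± 0.16 with Lcn2+Ent+Fe, while CYP2S1, higher with Ent, was at -0.29 ± 0.066 with Lcn2 (adjusted p = 0.138) and -0.24 ± 0.066 with Lcn2+Ent+Fe (0.196), against the direction expected.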
